A study of Mus musculus with 28 samples.

How the data were processed

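Total RNA of mouse tissues, sorted or isolated liver cells and liver organoids was labelled with Cy3 and hybridised to whole-genome Agilent arrays beside a mouse reference RNA labelled with Cy5. Per the file headers the deposited scanner files hold, for each spot, the median intensity of the spot and of its local background in both channels as read by Agilent Feature Extraction, with flags for outliers and for signals well above background. They also hold the log ratio that Feature Extraction wrote after background subtraction and dye normalization, deposited as log10 of Cy5 over Cy3. The file headers name Feature Extraction 10.5.1.1 and the processing notes 8.5.1.1. The deposited series matrix repeats that log10 ratio: it differed from the scanner files by at most 0.0000 on all 28 arrays, over 40625 to 41173 spots each. The files hold no mean intensity, so medians were used.

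Values were computed anew from the intensities as log2 of sample over reference, Cy3 over Cy5, in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, and dyes were balanced with loess within each array, with 1639 of 45018 spots, the controls, at weight 0. Outlier spots, 0.495% of all, were left out. Spots of a probe were averaged to 41174 probes. A probe was tested if it was well above background in Cy3 on at least 2 arrays, which left 31064 probes and 21032 genes. Of several probes of a gene, the one with the highest mean Cy3 signal stood for it. Gene names came from the files and a table of RefSeq genes (assembly GRCm38), used for names only: 16783 genes were named by a match and 4249 keep the name in the files. Positions are those of the files, in mm9.

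One linear model with a mean for each of the 13 groups was fitted to all 28 arrays with lmFit and eBayes, so that groups of 2 arrays and the single DM array share an estimate of the spread (15 residual and 4.37 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. All tests are two-sided. Gene lists, 29 with 426 of 432 members tested, were compared with all other genes by camera with a preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. Adjusted p-values of lists under other settings and without single arrays come from cameraPR on the moderated t. No comparison has 3 arrays in both groups, so regrouping the arrays could not test it. Arrays lay on 13 slides scanned on 9 days, and where a slide or day held both groups the sign of each called gene was compared within it. For called genes whose arrays did not overlap between the groups, that sign was fixed in advance.

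Groups, comparisons, gene lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 5 largest rises and 5 largest falls among called genes whose arrays do not overlap and which have a gene symbol, the 2 members with the largest rise and the 2 with the largest fall of each list described, and a fixed set of key genes. After the data were seen, the largest rises and falls were restricted to genes whose higher group was above background, and bounds were put on ratios. A few genes that the rule takes are not named. Other genes are marked where they appear.

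Calls were tested on simulated data with 200 of 21032 genes changed. For day 13 against day 3 after CCl4, 23.9, 88.1 and 95.5% of genes changed by 1, 2 and 3 log2 units were called, with 4 false calls. DM against EM organoids gave 19.4, 85.1 and 93.9% with 6, and adult liver against muscle 29.9, 89.6 and 95.5% with 5. The noisier Lgr5-sorted pair was left out. Alternatives were other normalizations (Agilent's log ratio, Cy3 alone scaled to the 75th percentile, quantiles between arrays), other filters, probe rules, tests and fold minimums, array weights, slide or scan day as random blocks, a replicate block, other undamaged livers, the 2 groups alone, and each array left out in turn.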

Results

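The series holds 28 mouse arrays with 2 colours, each with cRNA of a sample in Cy3 and a commercial mouse reference RNA in Cy5. They fall into 13 groups: liver organoids grown from single Lgr5-sorted cells in expansion medium (EM, 2 arrays) or differentiation medium (DM, 1 array), adult liver (2), whole liver (2), liver 3 and 13 days after carbon tetrachloride (CCl4, 2 each), isolated hepatocytes (2), duct cells sorted for a biliary surface antigen (2), cells sorted for Lgr5 at 6 days after CCl4 (2), muscle (3), white adipose tissue (3), brown adipose tissue (3) and pancreas (2). CCl4 is a toxin that kills hepatocytes around the central vein. Lgr5 is a Wnt-induced receptor for R-spondins that marks stem cells of several epithelia. The number of arrays limits the precision of every value. The labels call most arrays biological replicates. The files do not show whether these came from separate animals, so a p-value measures differences against the spread between arrays of a group, pooled over groups.

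The share of probes well above background in Cy3 was 46.8 and 60.9% on the adult liver arrays, 44.7 and 35.5% in whole liver, 40.1 and 33.1% in hepatocytes, and 56.6 and 39.5% in sorted duct cells. It was 53.8 and 31.4% on the EM arrays, 30.8% on the DM array, 61.5 and 62.7% at day 3 after CCl4 and 61.3 and 61.9% at day 13. Lgr5-sorted cells had the dimmest pair of liver arrays, at 21.0 and 18.5%. Muscle gave 51.8, 40.3 and 59.8%, white adipose tissue 50.1, 45.8 and 52.8%, brown adipose tissue 67.6, 69.1 and 65.2% and pancreas 17.7 and 44.0%. The Y-linked gene Ddx3y, picked after its values were seen, was above background on both adult liver, hepatocyte and day 3 arrays, whole liver replicate 1 and the DM array, and on no EM, duct, Lgr5-sorted or day 13 array. The labels do not give the sex of the animals, so it is confounded with the group where a comparison crosses this line: EM organoids with adult liver and with DM, duct and Lgr5-sorted cells with hepatocytes, and the times after CCl4. Whole liver lay on both sides, so sex is mixed into every comparison with it.

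Values given as a number ± another are log2 changes ± standard errors from limma, with the first group of a comparison over the second and the array numbers above as n. A gene that was well above background on no array of its lower group has a bound in place of a change, written "at least N-fold": the ratio left when its Cy3 signals in that group are raised to the percentile 5 of the detected probes of the array. Genes picked for the size of their change had arrays that did not overlap between the groups. Lists were tested with camera. Counts of list members and medians "with bounds" leave out those near background in the higher group, such medians set undetected members at their bounds, and the count adjusted over the list alone was the same where only 1 count is given.

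Lgr5, measured by a probe at 114888847 to 114888906 on chromosome 10 (mm9), had a mean log2 ratio to the reference of 4.15 ± 0.51 (SD, n = 2) in EM organoids. The DM array stood at -0.19, with Lgr5 not above background. Adult liver stood at 3.39 ± 0.06, day 13 after CCl4 at 3.36 ± 0.17, day 3 at 2.01 ± 0.42, hepatocytes at 1.24 ± 0.39 and whole liver at 0.44 ± 0.23. In Lgr5-sorted cells (0.15 ± 0.12) and sorted duct cells (-0.05 ± 0.09) the Lgr5 signal was above background on no array. Axin2, a negative feedback regulator of Wnt signalling, reached 2.37 ± 0.10 in EM organoids and was above background on no adult liver, whole liver, hepatocyte, duct or Lgr5-sorted array. Krt19 (chromosome 11, 100002392 to 100002451), a keratin of bile duct cells, stood at 3.28 ± 0.24 in EM organoids, 5.68 in the DM organoid, 3.01 ± 1.00 in duct cells and -3.61 ± 0.01 in adult liver.

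**Figure D1:**
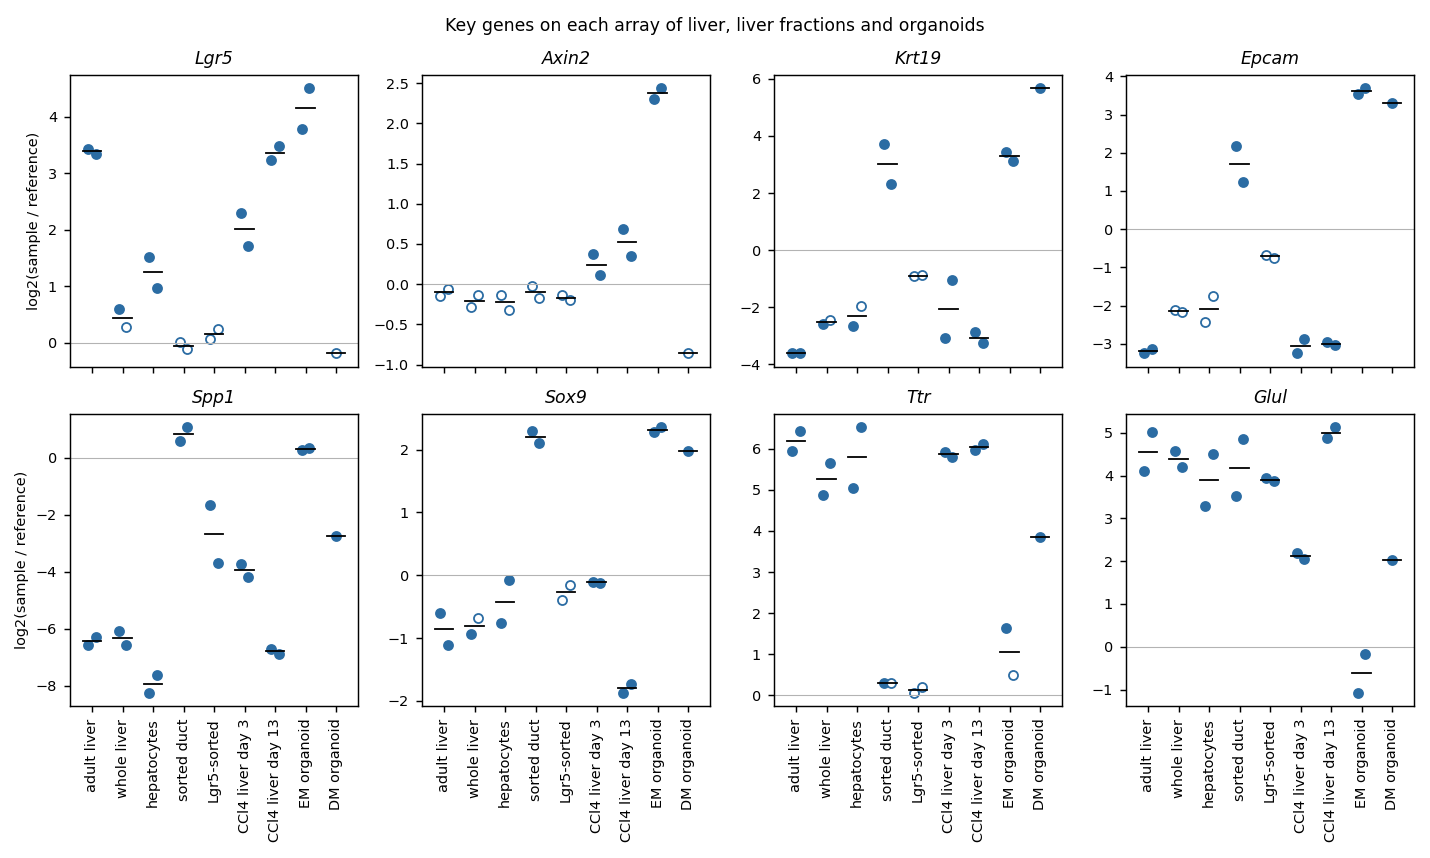
Log2 ratio of sample to reference for 8 marker genes on each liver, fraction and organoid array; filled points were well above background in Cy3, open points were not, and lines are group means. Lgr5 was open on both Lgr5-sorted arrays and on the DM array, and filled on both EM arrays at a mean of 4.15.

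Organoids in expansion medium were compared with adult liver, the tissue of origin, to ask which programme the cultured cells carried. They held far less of the hepatocyte transcripts and more of those of bile duct epithelium. Krt19 was at 6.89 ± 0.52, and Epcam, an epithelial adhesion molecule, at 6.81 ± 0.51. The neutrophil chemokine Cxcl5 was at least 691-fold higher, the antimicrobial lectin Reg3b at least 87.3-fold higher, and Gabrp, a GABA receptor subunit, at 8.38 ± 0.43. Cps1, the first enzyme of the urea cycle, was at least 349-fold lower. The aldo-keto reductase Akr1c6 was at least 695-fold lower, Cyp3a41a at least 368-fold lower, and the selenium carrier Selenop at -9.55 ± 0.52.

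Of the plasma proteins secreted by hepatocytes, 21 of 22 were lower (median -4.94, or -4.74 with bounds, adjusted p = 4.26e-11, adjusted p = 0.118 with an estimated correlation), among them antithrombin, Serpinc1 (-8.73 ± 0.64), and Apoh (at least 136-fold lower). For cytochrome P450 and other drug metabolism genes, 16 of 17 were lower (median -5.35, or -5.21 with bounds, adjusted p = 1.45e-12); the glucuronosyltransferase Ugt2b5 was at least 186-fold lower and the fatty acid hydroxylase Cyp4a14 at least 123-fold lower. In bile acid synthesis and transport, 14 of 14 were lower (median -5.59, or -4.75 with bounds, adjusted p = 2.95e-12), with the uptake carrier Slco1b2 at least 180-fold lower and the conjugating enzyme Baat at least 64.1-fold lower. Of hepatic transcription factors, 9 of 13 were lower (median -3.60, or -2.85 with bounds, adjusted p = 3.19e-05), including Creb3l3 (-5.71 ± 0.38) and the xenobiotic receptor Nr1i2 (at least 15.4-fold lower). In the cell cycle list, 30 of 33 were higher (median 2.30, adjusted p = 9.01e-16), led by the mitotic kinesin Kif20a (at 4.13 ± 0.28) and the replication helicase subunit Mcm6 (at 3.72 ± 0.29). For bile duct epithelium, 19 of 23 were higher (median 3.82, or 3.18 with bounds, adjusted p = 1.09e-14); Sox9, a transcription factor of duct cells, was at 3.18 ± 0.27.

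Wnt target genes went both ways, as 10 of 21 were higher and 5 lower (adjusted p = 0.0808); Cd44 (4.03 ± 0.59) and Myc (4.03 ± 0.27) were higher, and Glul, the glutamine synthetase of pericentral hepatocytes, and Tbx3 (-4.55 ± 0.35) were lower, Glul at -5.17 ± 0.41. The Wnt feedback gene Axin2 was at least 3.62-fold higher, whereas Lgr5 itself did not pass, at 0.76 ± 0.37 (adjusted p = 0.0994; 1.12 with adjusted p = 0.0464 without EM replicate 1). In the Notch pathway, 4 of 12 were higher and 3 lower (adjusted p = 0.415); the ligand Jag1 (2.09 ± 0.31) and its target Hes1 (1.90 ± 0.27) were higher and Heyl was at least 1.38-fold lower. In the fetal liver list, 1 of 9 was higher and 1 lower (adjusted p = 0.688), with Igf2 (1.59 ± 0.18) higher and Dlk1 (-1.12 ± 0.35) lower. Albumin was lower at -2.48 ± 0.95 (adjusted p = 0.0373), a call lost without any 1 of the 4 arrays. With Cy3 alone, which leaves out the reference channel, it stood at -13.49 (adjusted p = 6.01e-08).

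In all, limma called 6733 of 21032 genes, 3032 higher and 3701 lower, and 6728 with slide as a random block. No slide held both groups, but 1 scan day did, and there 6724 of the 6731 called genes with a value had the same sign.

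DM organoids are represented by 1 array, which is assumed to vary like the other groups. In differentiation medium the organoid had less Lgr5 and Axin2 and more of several genes of drug metabolism. Krt20, a keratin of differentiated intestinal cells, was at 8.41 ± 0.73, Clca1, a secreted protein of goblet cells, at least 176-fold higher, the cytochrome P450 genes Cyp2c65 at least 162-fold higher and Cyp2s1 at 7.05 ± 0.55, and the carboxylesterase Ces2b at 7.48 ± 0.58. Lgr5 was at least 3.9-fold lower and Axin2 at least 1.68-fold lower. Complement C3 was at -6.71 ± 0.61, the monocyte chemokine Ccl2 at -6.05 ± 0.67, Tmem45a at least 39.5-fold lower, the collagen gene Col14a1 at least 16.1-fold lower and the small nucleolar RNA Snord123 at least 18.2-fold lower.

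For drug metabolism genes, 7 of 17 were higher, or 8 adjusted over the list alone (median 1.59, or 1.67 with bounds, adjusted p = 1.21e-04, adjusted p = 0.453 with an estimated correlation), among them Cyp3a13 (5.18 ± 0.41) and Cyp2c29 (4.06 ± 0.56). In the list of hepatocyte secreted proteins, 4 of 22 were higher (adjusted p = 0.189); Apob was at least 15.2-fold higher and Apoa1 at least 7.3-fold higher, and Ttr, the thyroxine carrier transthyretin, at 2.79 ± 0.53. Albumin did not pass, at 2.43 ± 1.16 (adjusted p = 0.205), but did with Cy3 alone (6.50, adjusted p = 0.0125). Of bile acid genes 3 of 14 were higher (adjusted p = 0.0704), with the bile acid receptor Nr1h4 at 3.90 ± 0.49 and the export pump Abcc2 at least 3.73-fold higher. Among hepatic transcription factors 2 of 13 were higher (adjusted p = 0.118), of which Creb3l3 (3.54 ± 0.47) was the larger. In bile duct epithelium 4 of 23 were higher and 2 lower (adjusted p = 0.892); the secreted phosphoprotein Spp1 was lower at -3.06 ± 0.66 and the chloride channel Cftr at least 1.22-fold lower, while Anxa13 (3.34 ± 0.70) and Krt19 (2.40 ± 0.64) were higher, Krt19 with adjusted p = 0.0550 without EM replicate 2.

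Wnt target genes were lower as a group, with 2 of 21 higher and 7 lower (median -0.38, or -0.20 with bounds, adjusted p = 0.038, adjusted p = 0.272 with an estimated correlation); Tbx3 (3.68 ± 0.43) and Glul (2.65 ± 0.50) were the members that were higher. Of the cell cycle list, 3 of 33 were lower (median -0.44, or -0.37 with bounds, adjusted p = 0.0059, adjusted p = 0.553 with an estimated correlation), among them Mcm3 (-1.56 ± 0.31) and Mcm4 (-1.43 ± 0.36). Without EM replicate 2 both list tests missed the threshold, at adjusted p = 0.0736 each. In the Notch pathway 2 of 12 were higher (adjusted p = 0.636), Jag2 (1.56 ± 0.30) and Notch3 (1.45 ± 0.38). In the fetal liver list 1 of 9 was higher and 1 lower (adjusted p = 0.958), with Gpc3 (1.92 ± 0.57) higher and Igf2 at least 2.07-fold lower.

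The call covered 2144 genes, 1304 higher and 840 lower, 2210 with slide as a random block, and 1700 against the EM array of the same slide alone. On that slide all 2143 called genes with a value had the same sign, which was fixed in advance, as no called gene had arrays that overlapped. With Agilent's log ratio there were 572 higher and 588 lower, and Cy3 alone moved the median of all genes to 0.28. On the DM array the Y-linked gene Eif2s3y stood at 1.87 and Cyp4a12a, a P450 gene higher in male mouse liver, at 4.36. The EM arrays gave -2.97 and -2.64, and -0.10 and -0.51 (both genes picked after their values were seen), so medium cannot be separated here from the sex and line of the cultures.

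Set against adult liver, the DM organoid still lacked most hepatocyte transcripts and held high levels of duct genes. Krt19 was at 9.29 ± 0.64 and Krt20 at least 943-fold higher, Clca1 at least 273-fold higher, Cyp2s1 (8.68 ± 0.55) was higher, and the calcium-binding protein gene S100a6 was at 8.79 ± 0.54. Akr1c6 was at least 412-fold lower, Cps1 at least 178-fold lower, the bile acid carrier Slco1b2 at least 131-fold lower, and Rgn, a calcium-binding liver enzyme, at least 222-fold lower. Lgr5 was at least 2.3-fold lower.

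Among hepatocyte secreted proteins 17 of 22 were lower (median -4.61, or -3.00 with bounds, adjusted p = 3.86e-09, adjusted p = 0.178 with an estimated correlation); Apoh (at least 79.8-fold lower) and fibrinogen gamma, Fgg (at least 74.6-fold lower), were among them. For drug metabolism, 12 of 17 were lower, or 13 adjusted over the list alone (median -3.15, adjusted p = 6.55e-08, adjusted p = 0.103 with an estimated correlation), with Cyp4a14 at least 74.1-fold lower and Cyp2c70 at least 32.5-fold lower. For bile acid genes, 14 of 14 were lower (median -5.40, or -3.25 with bounds, adjusted p = 2.33e-11), Baat being at least 36.2-fold lower. Hepatic transcription factors were lower, with 9 of 13 lower (median -2.91, or -2.12 with bounds, adjusted p = 2.15e-04), such as Prox1 (at least 6.4-fold lower) and the receptor Nr1i3 (at least 8.73-fold lower). With whole liver in place of adult liver this list missed the threshold (adjusted p = 0.0672). For duct genes, 18 of 23 were higher (median 3.85, or 3.94 with bounds, adjusted p = 1.24e-15), led by Krt19 and by Prom1, a membrane protein of epithelial progenitors, which was at least 96.6-fold higher. In the cell cycle list 24 of 33 were higher (median 1.92, or 2.04 with bounds, adjusted p = 6.94e-13), including Kif20a (3.56 ± 0.34) and Mki67 (3.56 ± 0.38).

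Wnt targets were split, with 6 of 21 higher and 6 lower (adjusted p = 0.901): Ephb3 (4.19 ± 0.35) and Ccnd1 (3.94 ± 0.55) were higher, and Nkd1 was at least 4.94-fold lower. Of the Notch genes 4 of 12 were higher and 1 lower (adjusted p = 0.246), with Jag2 at least 7.14-fold higher, Hes1 (2.27 ± 0.33) higher and Hes5 at least 1.06-fold lower. Of the fetal liver list 1 of 9 was higher (adjusted p = 0.652), Gpc3 being at least 3.96-fold higher.

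The comparison called 5944 genes, 2914 higher and 3030 lower, or 5888 with slide as a random block. No slide or scan day held both groups, so batch and group cannot be told apart here. The median of all genes moved to -0.16 with Agilent's log ratio and to 0.22 with Cy3 alone.

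Sorted duct cells and hepatocytes shared slides. Duct cells had more Spp1 (at 8.76 ± 0.54) and Krt19 (at 5.32 ± 0.52), Epcam was at least 13.9-fold higher, and the actin-severing protein Gsn was at 9.72 ± 0.43. They also had more of the cytokine Il6 (at least 217-fold higher), the chemokine Cxcl1 (at 7.62 ± 0.81) and the heat shock gene Hspa1a (at 8.65 ± 0.93). Hepatocyte transcripts were lower, among them Rgn (-10.14 ± 0.60), Akr1c6 (-9.81 ± 0.51), the urinary protein gene Mup1 (at -9.33 ± 0.92) and Slco1b2 (-9.42 ± 0.69), and Cps1 was at least 369-fold lower.

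For bile duct epithelium, 18 of 23 were higher (median 2.62, or 2.24 with bounds, adjusted p = 4.96e-13), with Spp1 and Bicc1 (5.37 ± 0.22) highest and Sox9 (2.62 ± 0.27) among them. For hepatocyte secreted proteins, 20 of 22 were lower, or 21 adjusted over the list alone (median -5.34, adjusted p = 3.23e-16, adjusted p = 0.0536 with an estimated correlation), such as Serpinc1 (-8.83 ± 0.64) and Apoh (-8.79 ± 0.75). Genes of stellate cells and extracellular matrix were higher as well, with 19 of 22 higher (median 2.46, adjusted p = 8.54e-15), among them the proteoglycan Lum (at 6.91 ± 0.60) and the collagen Col1a2 (at 6.15 ± 0.58). For endothelium, 12 of 15 were higher, or 13 adjusted over the list alone (median 2.96, adjusted p = 2.64e-06, adjusted p = 0.182 with an estimated correlation); Vwf, the von Willebrand factor, was at least 31.4-fold higher and Emcn (4.14 ± 0.84) was higher. Immediate early and dissociation stress genes were higher throughout, with 14 of 14 higher (median 4.69, or 4.63 with bounds, adjusted p = 5.96e-10, adjusted p = 0.102 with an estimated correlation), Egr1 (6.72 ± 1.02) beside Hspa1a.

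Macrophage genes were mixed, as 3 of 20 were higher and 1 lower (adjusted p = 0.298): Cd14 (6.05 ± 0.45) and the lysozyme gene Lyz2 (at 3.28 ± 0.48) were higher and Cd5l (-3.06 ± 0.54) lower. Of lymphocyte genes 1 of 13 was higher and 1 lower (adjusted p = 0.884), with Lck at least 2.3-fold higher and Cd3e (-1.75 ± 0.42) lower. Wnt targets were split: 7 of 21 were higher and 3 lower (adjusted p = 0.325), with Myc (3.67 ± 0.27) and Nkd1 (3.20 ± 0.41) higher, and Rnf43 (-2.07 ± 0.32) and Lgr4 (-1.61 ± 0.40) lower. Lgr5 was at least 1.36-fold lower, a call lost without hepatocyte replicate 1 or duct replicate 2.

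In all 4889 genes were called, 2509 higher and 2380 lower, and 4937 with slide as a random block. On both slides that held the groups, 4515 of the 4515 called genes with a value kept their sign. The count was 7677 with Agilent's log ratio and 7395 with Cy3 alone, with the median of all genes moved to -0.26 under Cy3 alone.

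Lgr5-sorted cells, the only fraction after CCl4, were compared with hepatocytes and duct cells, so sort and CCl4 cannot be separated. The lysozyme gene Lyz2 was at 9.86 ± 0.48, the lysosomal protease gene Ctss at 8.86 ± 0.65 and the actin-binding thymosin Tmsb4x at 8.76 ± 0.44. Hspa1a (7.16 ± 0.93) and the signalling regulator Rgs2 (at 7.13 ± 0.57) were higher too. Cps1 was at least 166-fold lower, the urinary protein genes Mup5 and Mup10 at least 245-fold lower and at least 162-fold lower, the hydrolase Aadac at -8.93 ± 0.68, and Slco1b2 (-8.66 ± 0.69) was lower. Lgr5 was above background on neither Lgr5-sorted array and was called lower (adjusted p = 0.029) with no fold beyond the detection floor. The call was lost without hepatocyte replicate 1 or either Lgr5-sorted array.

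The macrophage list was higher, with 17 of 20 higher (median 4.36, or 4.60 with bounds, adjusted p = 3.37e-11, adjusted p = 0.0867 with an estimated correlation). For hepatocyte secreted proteins, 19 of 22 were lower, or 20 adjusted over the list alone (median -5.65, or -5.13 with bounds, adjusted p = 9.76e-18), among them Apob (-7.82 ± 0.41) and Apoh (-7.77 ± 0.75). Stellate and matrix genes were higher, with 9 of 22 higher, or 10 adjusted over the list alone (median 1.57, or 1.92 with bounds, adjusted p = 1.63e-06, adjusted p = 0.0988 with an estimated correlation), led by Vim (5.49 ± 0.40) and Col1a2 (3.86 ± 0.58). In the immediate early and stress list, 13 of 14 were higher (median 2.94, or 2.89 with bounds, adjusted p = 6.24e-06, adjusted p = 0.273 with an estimated correlation), with Nr4a1 (5.81 ± 1.13). For endothelium 4 of 15 were higher (adjusted p = 0.0711), including Cdh5 (3.84 ± 0.64) and Flt1 (3.13 ± 0.90). Without Lgr5-sorted replicate 1 that endothelial list passed (median 3.02, adjusted p = 2.11e-04).

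Duct genes did not move as a group: 3 of 23 were higher and 2 lower (adjusted p = 0.31), with Spp1 (5.26 ± 0.54) and Bicc1 (2.40 ± 0.22) higher, Onecut2 at least 7.69-fold lower and Krt23 at least 1.34-fold lower. Lymphocyte genes gave 1 of 13 higher and 1 lower (adjusted p = 0.666), Cd79b (2.22 ± 0.32) higher and Cd3e (-1.25 ± 0.42) lower. Of Wnt targets 3 of 21 were higher and 4 lower (adjusted p = 0.995): Cd44 (3.15 ± 0.59) and Myc (2.29 ± 0.27) were higher, Rnf43 was at least 5.28-fold lower and Lgr4 at least 3.24-fold lower.

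Together 4523 genes were called, 2531 higher and 1992 lower, and 4575 with slide as a random block. On both slides 4159 of 4170 called genes with a value kept their sign. By Agilent's log ratio 2821 were higher and 4169 lower, Cy3 alone called 7717 genes and moved the median of all genes to 0.73, and a fit of these 2 groups alone called 2837.

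Against duct cells, Lgr5-sorted cells had more macrophage and fewer duct transcripts. Cd5l and Clec4f, markers of the resident macrophages of the liver, were at 9.12 ± 0.54 and at 6.36 ± 0.80, the scavenger receptor Marco was at 7.24 ± 0.91, Lyz2 (6.58 ± 0.48) and Ctss (6.57 ± 0.65) were higher. Plet1, a surface protein of epithelial progenitors, was at least 61.2-fold lower, the keratin gene Krt23 at least 31.9-fold lower, the hexokinase gene Hkdc1 at least 20.3-fold lower, and Il6 (-7.15 ± 0.58) and Lum (-6.17 ± 0.60) were lower.

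Of duct genes 18 of 23 were lower (median -2.48, or -2.13 with bounds, adjusted p = 4.51e-23), but low signal alone could hide 12 members. Anxa13 was at least 14.5-fold lower. For macrophages, 14 of 20 were higher and 1 lower, or 16 higher and 1 lower adjusted over the list alone (median 3.63, or 4.08 with bounds, adjusted p = 4.66e-13, adjusted p = 0.0974 with an estimated correlation), and Cd14 (-2.55 ± 0.45) was the lower member. Stellate and matrix genes were lower, with 12 of 22 lower, or 13 adjusted over the list alone (median -1.33, or -1.38 with bounds, adjusted p = 1.10e-11), among them Dcn (-3.38 ± 0.55). Endothelial genes were lower, with 4 of 15 lower, or 5 adjusted over the list alone (median -1.29, or -0.61 with bounds, adjusted p = 3.90e-05, adjusted p = 0.342 with an estimated correlation), such as Vwf (-4.02 ± 0.40) and Eng (-3.29 ± 0.27). Without Lgr5-sorted replicate 1 the endothelial test missed the threshold (adjusted p = 0.213). Immediate early and stress genes were lower, with 3 of 14 lower, or 4 adjusted over the list alone (median -1.49, adjusted p = 5.85e-05, adjusted p = 0.371 with an estimated correlation), among them Junb (-3.68 ± 0.48) and Ier3 (-2.75 ± 0.71). That direction rested on Lgr5-sorted replicate 2, without which the median was 0.37. List medians were 0.83 on one slide and -3.68 on the other.

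Wnt targets were lower, with 2 of 21 lower (median -0.27, or -0.28 with bounds, adjusted p = 0.0284, adjusted p = 0.0791 with an estimated correlation), among them Nkd1 (-2.50 ± 0.41) and Myc (-1.38 ± 0.27). Of cell cycle genes 17 of 33 were higher (median 1.36, or 1.40 with bounds, adjusted p = 3.12e-16), confounded with CCl4. Hepatocyte secreted proteins were mixed, as 2 of 22 were higher and 3 lower (adjusted p = 0.807): Ahsg (3.14 ± 0.90) and F2 (2.98 ± 0.57) were higher, Ambp (-3.56 ± 0.98) and Vtn (-2.29 ± 0.70) lower. Of lymphocyte genes 1 of 13 was higher (adjusted p = 0.703), the B-cell gene Cd79b (at 1.76 ± 0.32).

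The comparison called 2396 genes, 1263 higher and 1133 lower, and 2487 with slide as a random block; 2240 of 2249 with a value kept their sign on both slides. Agilent's log ratio gave 1480 higher and 3517 lower and Cy3 alone 4501 higher and 2124 lower. They moved the median of all genes to -0.21 and 0.66. A fit of the 2 groups alone called no gene (limma, 3862 at an unadjusted p under 0.05).

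Between isolated hepatocytes and whole liver 158 genes passed. The sulfotransferase Sult2a2 was at least 47.9-fold lower in hepatocytes (log2 -4.45 and -9.16 on the 2 slides), and female mouse liver expresses it more than male. The aldose reductase gene Akr1b3 was lower (at -3.14 ± 0.30), and the retinoic acid hydroxylase Cyp26a1 (at 2.47 ± 0.31) and the ribosomal protein gene Mrps12 (at 2.30 ± 0.30) were higher. The homeobox gene Meox2 was at least 2.07-fold higher. Of the other genes picked by size, 4 were called with all arrays and not without hepatocyte replicate 2 or whole liver replicate 2: Arsa (2.38 ± 0.38) (adjusted p = 0.0556 and 0.0625), Clstn3 (2.27 ± 0.48) (0.0909 and 0.375), Cyp2b13 (-3.55 ± 0.77) (0.172 and 0.202) and Acot4 (-3.03 ± 0.60) (0.118 and 0.215). Clstn3 and Cyp2b13 were lost without hepatocyte replicate 1 as well (adjusted p = 0.112 and 0.0557). Xist, the RNA of the inactive X chromosome, stood at -2.14 and -1.92 in the hepatocytes and at -1.85 and 2.53 in the whole liver arrays, a gene looked at after its values were seen.

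Macrophage genes were lower in hepatocytes, with 2 of 20 lower, or 9 adjusted over the list alone (median -1.17, or -1.55 with bounds, adjusted p = 5.02e-08, adjusted p = 0.805 with an estimated correlation), among them Vsig4 (-2.79 ± 0.56) and Lyz2 (-2.43 ± 0.48). Of stellate and matrix genes 1 of 22 was lower, or 3 adjusted over the list alone (adjusted p = 0.0572), the retinol esterifying enzyme gene Lrat (at -1.73 ± 0.27), and the list passed without hepatocyte replicate 2 (adjusted p = 0.0059). For hepatocyte secreted proteins, none of 22 passed (1 at an unadjusted p under 0.05 in limma, adjusted p = 0.216), Fga standing at 0.91 ± 0.36 and F2 at 0.74 ± 0.57; without whole liver replicate 2 or hepatocyte replicate 1 this list passed (medians 1.08 and 1.36, adjusted p = 2.66e-05 and 4.83e-07). In the endothelial list none of 15 passed (1 at an unadjusted p under 0.05 in limma, adjusted p = 0.0572), with Clec4g at -1.11 ± 0.99 and Robo4 at -1.10 ± 1.08; without those same arrays it passed too (adjusted p = 0.0147 and 0.0171). Bile duct genes gave no call: none of 23 passed (3 at an unadjusted p under 0.05 in limma, adjusted p = 0.216), Spp1 at -1.60 ± 0.54 and Anxa13 near background. For Wnt targets none of 21 passed, or 1 lower adjusted over the list alone (2 at an unadjusted p under 0.05 in limma, adjusted p = 0.994), Ccnd1 at -1.72 ± 0.45 and Nkd1 at -0.83 ± 0.41. Lymphocyte and stress genes did not pass either: none of 13 passed (0 at an unadjusted p under 0.05 in limma, adjusted p = 0.825) for lymphocytes, Cd3e at 0.76 ± 0.42, and none of 14 passed (0 at an unadjusted p under 0.05 in limma, adjusted p = 0.348) for stress genes, Junb at 0.93 ± 0.48 and Zfp36 at 0.75 ± 0.67.

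Of the 158 genes, 77 were higher and 81 lower, or 217 with slide as a random block, and all 144 with a value kept their sign on both slides. The count was 461 without whole liver replicate 1, 55 without whole liver replicate 2 and 101 without hepatocyte replicate 2. Agilent's log ratio gave 80 higher and 329 lower and Cy3 alone, which moved the median of all genes to 0.18, 63 higher and 145 lower. A fit of the 2 groups alone called no gene (limma, 1582 at an unadjusted p under 0.05).

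Liver 3 days after CCl4 was compared with whole liver. Afp, alpha-fetoprotein of fetal liver, was at 6.87 ± 0.99, the adhesion gene Cdh1 at 4.78 ± 0.57, the steroid-metabolising reductase Akr1c18 at 4.82 ± 0.55, the surface antigen gene Ly6d at 4.84 ± 0.52, and Ptprz1 (5.03 ± 1.12), a receptor phosphatase gene, was higher (adjusted p = 0.0599 without whole liver replicate 1). The sulfotransferases Sult2a8 and Sult2a2 were at -4.26 ± 0.49 and at -5.49 ± 0.81. With adult liver in place of whole liver Sult2a2 changed sign, to 0.95. Dct (-4.82 ± 1.02) was lower, with adjusted p = 0.0886 without whole liver replicate 2, and Sult3a1 was at least 39.4-fold lower, with adjusted p = 0.109 without it and 0.0677 or 0.0682 without a day 3 array. Sult2a2 and Sult3a1 stood at 4.45 and 1.37 on whole liver replicate 1 and at 9.03 and 9.92 on replicate 2, so their falls cannot be separated from sex.

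The cell cycle list was higher, with 26 of 33 higher (median 2.01, adjusted p = 2.74e-30), including the mitotic genes Cdc20 (4.60 ± 0.34) and Birc5 (4.10 ± 0.35). For stellate cells and matrix, 11 of 22 were higher, or 12 adjusted over the list alone (median 1.31, or 1.29 with bounds, adjusted p = 4.95e-07, adjusted p = 0.152 with an estimated correlation), with the collagens Col3a1 (3.67 ± 0.42) and Col1a1 (3.59 ± 0.35). For pericentral hepatocytes, 4 of 11 were lower (median -0.76, or -0.89 with bounds, adjusted p = 1.87e-04, adjusted p = 0.101 with an estimated correlation); the glutamate transporter gene Slc1a2 (at -3.71 ± 0.28) and ornithine aminotransferase, Oat (-2.72 ± 0.28), were lowest. For drug metabolism, 3 of 17 were lower, or 6 adjusted over the list alone (median -0.77, adjusted p = 0.011, adjusted p = 0.536 with an estimated correlation), with Cyp2c37 (-3.39 ± 0.42) and Cyp4a10 (-2.29 ± 0.53), and without whole liver replicate 2 adjusted p = 0.255. For macrophages, 3 of 20 were higher (median 0.82, adjusted p = 0.0047, adjusted p = 0.551 with an estimated correlation); the chemokine receptor Ccr2 was at least 3.52-fold higher and Lyz2 at 1.95 ± 0.48, and without whole liver replicate 1 the list gave adjusted p = 0.321. For bile duct genes, 4 of 23 were higher (median 0.39, or 0.50 with bounds, adjusted p = 0.0197, adjusted p = 0.498 with an estimated correlation), among them Prom1 (3.43 ± 0.46) and Pkhd1 (2.85 ± 0.27), and without the same array adjusted p = 0.0785. In the acute phase list 1 of 13 was higher (adjusted p = 0.167), the iron-binding Lcn2 (at least 9.43-fold higher), and that list passed without day 3 replicate 2 or whole liver replicate 2 (adjusted p = 0.0300 and 0.0330).

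Of Wnt targets 2 of 21 were higher and 1 lower, or 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.736): Ccnd1 (2.47 ± 0.45) was higher and Glul (-2.26 ± 0.41) lower. Lgr5 was higher at 1.57 ± 0.37 (adjusted p = 0.0064), and lost the call without day 3 replicate 1 (0.101) or whole liver replicate 2 (0.0617). Against adult liver Lgr5 was lower instead, at -1.39 (adjusted p = 0.0137).

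The call covered 1915 genes, 1391 higher and 524 lower, or 1830 with slide as a random block. No slide or scan day held both groups, so batch and group cannot be told apart. Without day 3 replicate 1 or 2 the count was 1132 and 1201. Cy3 alone, which moved the median of all genes to -0.26, gave 1067 higher and 1660 lower, and adult liver as the comparator 1111 higher and 714 lower.

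Liver 13 days after CCl4 was set beside whole liver in the same way. Higher were the copper chaperone gene Cox17 (at 4.19 ± 0.49), the transcription factor gene Klf2 (at 3.48 ± 0.49) and the glycogen-targeting subunit gene Ppp1r3g (at 3.41 ± 0.57), and Akr1b3 (-2.48 ± 0.26) was lower, though it stood at 0.23 against adult liver. Another 6 genes picked by size lost their calls without a day 13 array or whole liver replicate 1: Ptprz1 (5.0 ± 1.12) and Grn (3.72 ± 0.83) were higher, Cyp4a12a (-3.21 ± 0.73), Hsd3b4 (-2.25 ± 0.62) and the Y-linked genes Eif2s3y (at -3.09 ± 0.66) and Ddx3y (at least 5.84-fold lower) lower. Without whole liver replicate 1 their adjusted p values were 0.0929, 0.109, 0.173, 0.480, 0.0845 and 0.0866 in that order. Without day 13 replicate 1 they were 0.0609, 0.0728, 0.0932, 0.102, 0.0619 and 0.0703, and without replicate 2 0.0842, 0.0757, 0.0645, 0.206, 0.0584 and 0.0575.

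Lgr5 was higher at 2.92 ± 0.37 (adjusted p = 1.25e-04), but stood at -0.04 against adult liver. Of Wnt targets 3 of 21 were higher, or 6 adjusted over the list alone (adjusted p = 0.278), the transcription factor gene Sp5 (1.66 ± 0.32) among them, which stood at -1.09 against adult liver. The cell cycle list was lower, with 4 of 33 lower (median -0.56, or -0.45 with bounds, adjusted p = 1.98e-05, adjusted p = 0.846 with an estimated correlation), such as Ccnb1 (-1.24 ± 0.22) and Ube2c (-1.08 ± 0.33), but its median was 0.00 (adjusted p = 0.982) against adult liver. For drug metabolism 2 of 17 were higher, or 2 higher and 3 lower adjusted over the list alone (adjusted p = 0.914), namely Cyp2b10 (2.37 ± 0.37) and Cyp3a13 (1.24 ± 0.34). Of matrix genes 3 of 22 were higher, or 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.461), with Col3a1 (1.40 ± 0.42) and Lrat (1.27 ± 0.27). Of bile duct genes 1 of 23 was higher, or 3 adjusted over the list alone (adjusted p = 0.757), Pkhd1 (1.78 ± 0.27). Of pericentral genes 1 of 11 was higher (adjusted p = 0.914), the ammonium transporter gene Rhbg (at 2.30 ± 0.64). Agilent's log ratio turned Cyp3a13 (-0.38) and Rhbg (-0.05), and Cy3 alone turned Lrat (-0.48). Against adult liver these stood at -0.0010, -0.0002 and -0.29. For macrophage genes none of 20 passed (0 at an unadjusted p under 0.05 in limma, adjusted p = 0.267), C1qb at 1.66 ± 0.83 and C1qa at 1.47 ± 0.96, and without whole liver replicate 2 the list passed (median 0.96, adjusted p = 0.0113). In the acute phase list none of 13 passed (1 at an unadjusted p under 0.05 in limma, adjusted p = 0.876), Orm1 at 1.30 ± 0.58 and Saa1 at -0.89 ± 0.45.

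The call covered 991 genes, 690 higher and 301 lower, 884 with slide as a random block, and 690 higher and 176 lower among genes above background in the higher group. No slide or scan day held both groups, and batch and group cannot be told apart. Without day 13 replicate 1 or 2 it was 475 and 401. The count was 414 with Agilent's log ratio, Cy3 alone, which moved the median of all genes to -0.18, gave 68 higher and 128 lower, and adult liver as the comparator 120 higher and 179 lower.

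The times after CCl4 shared a slide, but sex is confounded with time. Cell division genes and Afp were lower at day 13: Afp was at -7.38 ± 0.99, Birc5 (-4.49 ± 0.35), Cdc20 (-4.44 ± 0.34) and the phosphatase gene Cdkn3 (at -4.38 ± 0.33) were lower, and D17H6S56E-5 was at -4.53 ± 0.26. Genes that differ between the sexes were among the largest rises: the sulfotransferase Sult2a2 was at 5.90 ± 0.81, the hydroxyacid oxidase Hao2 at least 61.1-fold higher, the transporter gene Slc22a26 at 6.43 ± 0.93 and Xist at least 59.5-fold higher. Ddx3y stood at 2.27 and 2.02 on the day 3 arrays, and at -1.86 and -1.71 on the day 13 arrays.

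**Figure D2:**
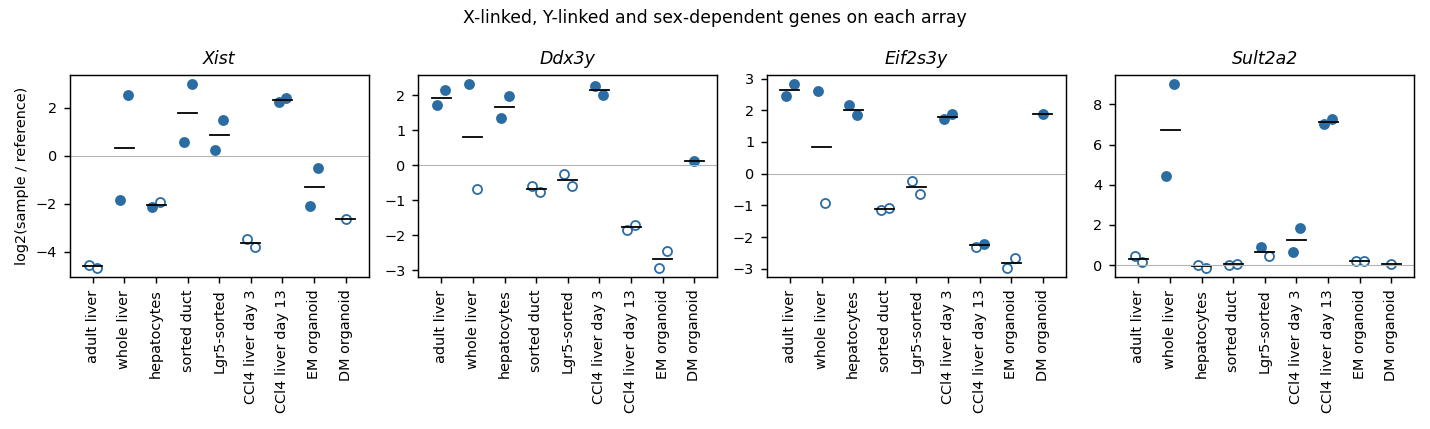
Log2 ratio of sample to reference for the X-inactivation gene Xist, the Y-linked genes Ddx3y and Eif2s3y and the sex-dependent liver gene Sult2a2 on each liver, fraction and organoid array; filled points were well above background, open points were not, and lines are group means. At day 13 Xist stood at 2.26 and 2.43 and Ddx3y was open, and at day 3 Xist was open and Ddx3y stood at 2.27 and 2.02.

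The cell cycle list was lower at day 13, with 29 of 33 lower, or 30 adjusted over the list alone (median -2.39, adjusted p = 1.77e-60). For stellate cells and matrix, 8 of 22 were lower, or 10 adjusted over the list alone (median -0.91, adjusted p = 1.68e-08, adjusted p = 0.122 with an estimated correlation), with Col1a1 (-2.88 ± 0.35) and Col3a1 (-2.27 ± 0.42). For pericentral hepatocytes, 4 of 11 were higher (median 0.31, or 0.35 with bounds, adjusted p = 5.55e-05, adjusted p = 0.0677 with an estimated correlation), including Slc1a2 (4.31 ± 0.28) and Rhbg (3.03 ± 0.64). For drug metabolism, 4 of 17 were higher (median 0.32, adjusted p = 0.0029, adjusted p = 0.416 with an estimated correlation), with Cyp4a10 (2.98 ± 0.53) and Cyp2c37 (2.81 ± 0.42). For bile duct genes, 5 of 23 were lower (median -0.38, or -0.44 with bounds, adjusted p = 0.0161, adjusted p = 0.349 with an estimated correlation), among them Spp1 (-2.84 ± 0.54) and Prom1 (-2.08 ± 0.46). Without day 3 replicate 2 the duct list missed the threshold (adjusted p = 0.0613), and Prom1 did without day 13 replicate 1 (0.151) or day 3 replicate 1 (0.0779).

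Wnt targets were higher, with 5 of 21 higher and 1 lower (median 0.17, adjusted p = 0.0492, adjusted p = 0.122 with an estimated correlation), among them Glul (2.88 ± 0.41) and Tnfrsf19 (2.00 ± 0.38) higher and Ccnd1 (-2.69 ± 0.45) lower. That call was lost without day 13 replicate 2 (adjusted p = 0.0534) or day 3 replicate 2 (0.0595). Of macrophage genes 1 of 20 was lower (adjusted p = 0.0534), Ccr2 (-2.61 ± 0.35). In the acute phase list 1 of 13 was lower (adjusted p = 0.16), Lcn2 (-3.58 ± 0.35), and the list passed without day 3 replicate 2 (median -0.36, adjusted p = 0.0311).

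All arrays of both times lay on 1 slide, so the signs within it repeat the calls and check nothing. The call covered 1185 genes, 445 higher and 740 lower, or 1243 with slide as a random block. It was 777 without day 13 replicate 2.

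EM organoids were set beside Lgr5-sorted cells, which alone followed CCl4. Duct genes and several others were higher in the organoids: Gabrp was at least 181-fold higher, Plet1 at least 88.4-fold higher, the surfactant protein gene Sftpd at least 76.6-fold higher, the tight-junction trafficking gene Mal2 at least 32.1-fold higher and Palmd at least 142-fold higher. Lgr5 was at least 4.9-fold higher and the Wnt target Sp5 at least 19-fold higher. Lyz2 (-13.86 ± 0.48), the lipid carrier gene Apoe (at -11.69 ± 0.56) and Selenop (-11.45 ± 0.52) were lower, Ctss was at least 4000-fold lower and Cd5l at least 871-fold lower.

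For bile duct epithelium, 22 of 23 were higher (median 3.63, or 2.98 with bounds, adjusted p = 2.52e-20); Prom1 was at least 28.8-fold higher and Krt23 at least 18.3-fold higher. Hepatic transcription factors were higher, with 7 of 13 higher and 1 lower, or 8 higher and 1 lower adjusted over the list alone (median 1.46, adjusted p = 0.0019); Foxa2 was at least 25.2-fold higher, while Creb3l3 (-1.57 ± 0.38) was lower. Of Wnt targets 11 of 21 were higher and 2 lower (median 1.1, adjusted p = 0.0189), Glul (-4.52 ± 0.41) and Nkd1 (-2.11 ± 0.41). For macrophages, 1 of 20 was higher and 16 lower (median -6.53, or -5.70 with bounds, adjusted p = 1.38e-11, adjusted p = 0.114 with an estimated correlation). For the fetal liver list, 3 of 9 were lower (median -2.19, or -2.46 with bounds, adjusted p = 0.0229, adjusted p = 0.351 with an estimated correlation), with Dlk1 (-3.49 ± 0.35) and Ctsc (-2.71 ± 0.65). With Agilent's log ratio the calls for transcription factors, Wnt targets and fetal genes were lost (adjusted p = 0.240, 0.0588 and 0.351). With Cy3 alone the first and last were (0.172 and 0.647).

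Cell cycle genes gave 4 of 33 higher and 2 lower (adjusted p = 0.443): Kif20a was at least 3.73-fold higher and Mcm7 (1.59 ± 0.23) was higher, and E2f1 (-1.14 ± 0.23) and Bub1 (-1.03 ± 0.28) were lower. Of Notch genes 3 of 12 were higher and 2 lower (adjusted p = 0.918); Jag1 was at least 3.68-fold higher, Hes1 at 1.48 ± 0.27, and Hey1 (-3.75 ± 0.42) and Notch2 (-2.05 ± 0.36) were lower. Hepatocyte secreted proteins gave 1 of 22 higher and 4 lower (adjusted p = 0.279), with Trf (2.94 ± 0.76) higher, Alb (-5.0 ± 0.95) lower and Ahsg at least 35-fold lower. For drug metabolism 1 of 17 was higher and 1 lower, or 1 higher adjusted over the list alone (adjusted p = 0.846), Cyp3a13 higher (adjusted p = 4.87e-04) with no fold beyond the detection floor and Cyp2c70 (-1.29 ± 0.45) lower. For bile acid genes 1 of 14 was lower (adjusted p = 0.484), the phospholipid exporter gene Abcb4 (-3.16 ± 0.37).

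The call covered 5183 genes, 2140 higher and 3043 lower, or 5167 with slide as a random block, and 2134 higher and 2056 lower among genes above background in the higher group. No slide or scan day held both groups, so batch and group cannot be told apart. Agilent's log ratio gave 4550 higher and 3198 lower, and Cy3 alone, which moved the median of all genes to -0.96, 3608 higher and 8859 lower.

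Organoids in expansion medium and freshly sorted duct cells had Krt19 and Sox9 at similar levels (differences of 0.27 ± 0.52, adjusted p = 0.739, and 0.11 ± 0.27, adjusted p = 0.786), which does not show that they were equal. Reg3b was at least 76.3-fold higher, Reg1 at least 53.4-fold higher and Reg3g at least 30.4-fold higher. Gabrp (6.31 ± 0.43) and Sp5 (5.76 ± 0.32) were higher and Lgr5 was at least 10.2-fold higher. Matrix genes, Cxcl1 and Il6 were lower: Cxcl1 was at least 958-fold lower, Il6 at least 334-fold lower, Lum at least 291-fold lower, the proteoglycan gene Srgn at least 278-fold lower, and Dcn (-10.93 ± 0.55) was lower.

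For stellate cells and matrix, 21 of 22 were lower (median -4.69, or -4.51 with bounds, adjusted p = 9.65e-21). For the cell cycle list, 24 of 33 were higher (median 1.57, adjusted p = 1.46e-09, adjusted p = 0.275 with an estimated correlation), with Mcm6 (3.85 ± 0.36) and Kif20a (3.33 ± 0.28). For bile duct epithelium, 11 of 23 were higher and 1 lower, or 12 higher and 1 lower adjusted over the list alone (median 1.00, adjusted p = 5.54e-04, adjusted p = 0.291 with an estimated correlation), Prom1 (5.14 ± 0.46) higher and Anxa13 (-2.47 ± 0.57) lower. This duct call was lost with Agilent's log ratio (adjusted p = 0.448) and Cy3 alone (0.0788). For the Notch pathway, 7 of 12 were lower (median -1.38, or -0.57 with bounds, adjusted p = 0.0099, adjusted p = 0.3 with an estimated correlation), such as Hey1 (-3.64 ± 0.42) and Notch3 (-2.47 ± 0.31). For the fetal liver list, 3 of 9 were lower (median -0.98, or -0.82 with bounds, adjusted p = 0.0349, adjusted p = 0.308 with an estimated correlation), with Dlk1 (-2.09 ± 0.35) and Igf2bp1 (-1.67 ± 0.20).

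Wnt targets were split: 7 of 21 were higher and 4 lower (adjusted p = 0.199), with Glul (-4.80 ± 0.41) and Nkd1 (-4.61 ± 0.41) lower. Hepatic transcription factors gave 6 of 13 higher and 2 lower (adjusted p = 0.164): Foxa2 (2.54 ± 0.52) was higher, Creb3l3 (-1.53 ± 0.38) lower and Nr5a2 at least 2.06-fold lower. For hepatocyte secreted proteins 2 of 22 were higher and 6 lower (adjusted p = 0.315), Trf (4.26 ± 0.76) and Hpx (1.75 ± 0.54) higher, Fgg (-4.33 ± 1.14) lower and Vtn at least 5.88-fold lower. In bile acid genes 3 of 14 were lower (adjusted p = 0.315), with Abcb4 (-2.65 ± 0.37) and Cyp7b1 (at least 6.74-fold lower). For drug metabolism none of 17 passed (2 at an unadjusted p under 0.05 in limma, adjusted p = 0.96), Por at -0.71 ± 0.40.

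The call covered 5604 genes, 2650 higher and 2954 lower, and the same number with slide as a random block. No slide or scan day held both groups, so batch and group cannot be told apart. The median of all genes moved to -0.13 with Agilent's log ratio and to -0.32 with Cy3 alone.

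Whole liver and adult liver are sets of undamaged liver deposited apart, and their difference measures the sets. Sult2a2, a gene that female mouse liver expresses more, was at least 64.3-fold higher (log2 ratios of 4.45 and 9.03 on the whole liver arrays). Xist was at least 21.2-fold higher, with adjusted p = 0.194 without whole liver replicate 2 and 0.0640 without adult liver replicate 2. Sult3a1 (at least 28.1-fold higher) and A1bg (at least 8.03-fold higher) lost their calls without whole liver replicate 2 (adjusted p = 0.194 and 0.882) or adult liver replicate 1 (0.0872 and 0.142) or 2 (0.0791 and 0.166). The lipid droplet genes Cidea (at -4.97 ± 0.86) and Cidec (at -4.25 ± 0.47), the bile acid enzyme gene Cyp8b1 (at -4.01 ± 0.47) and the transcription factor gene Olig1 (at -3.93 ± 0.25) were lower in whole liver. Trim12a (-3.53 ± 0.66) was lower too, with adjusted p = 0.0503 without whole liver replicate 2.

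Endothelial genes were lower, with 4 of 15 lower, or 6 adjusted over the list alone (median -1.50, adjusted p = 3.37e-04, adjusted p = 0.959 with an estimated correlation), among them Cdh5 (-2.13 ± 0.64) and Tie1 (-1.61 ± 0.34). Of Wnt targets 4 of 21 were lower, or 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.679), among them Lgr5 (-2.95 ± 0.37) and Sp5 (-2.75 ± 0.32); with Cy3 alone Lgr5 gave adjusted p = 0.0700. Matrix genes gave 3 of 22 higher and 1 lower (adjusted p = 0.152), Lox (1.27 ± 0.39) and Loxl1 (1.11 ± 0.32) higher and Lrat (-1.56 ± 0.27) lower, though Lrat stood at 0.34 with Cy3 alone. Of bile duct genes 1 of 23 was lower (adjusted p = 0.919), Pkhd1 (-1.24 ± 0.27). For lymphocytes 2 of 13 were lower (adjusted p = 0.429), Nkg7 (-1.95 ± 0.46) and Cd3d (-1.08 ± 0.32), and the list passed without adult liver replicate 1 (median -0.54, adjusted p = 0.00180). For macrophages none of 20 passed (1 at an unadjusted p under 0.05 in limma, adjusted p = 0.429), C1qb at -2.16 ± 0.83 and C1qa at -1.31 ± 0.96; it passed without whole liver replicate 2 (median -0.83, adjusted p = 0.0328). For hepatocyte secreted proteins none of 22 passed (4 at an unadjusted p under 0.05 in limma, adjusted p = 0.103), Ahsg at 1.82 ± 0.90 and Apoa2 at 1.78 ± 0.72; without whole liver replicate 1 the list passed (median 1.53, adjusted p = 0.00120). Of stress genes none of 14 passed (0 at an unadjusted p under 0.05 in limma, adjusted p = 0.919), Nr4a1 at -1.29 ± 1.13.

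The call covered 1371 genes, 474 higher and 897 lower, or 1343 with slide as a random block, and 286 higher and 897 lower among genes above background in the higher group. No slide or scan day held both sets. Without whole liver replicate 2 or adult liver replicate 2 it was 830 and 849. It was 261 with Agilent's log ratio, Cy3 alone, which moved the median of all genes to 0.31, gave 509 higher and 277 lower, and a fit of the 2 groups alone called 9.

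A set of liver-enriched genes was fixed as those at least 2 log2 units higher in adult liver than in each of muscle, white adipose tissue, brown adipose tissue and pancreas. It held 758 genes, and the adult liver arrays that chose it make other groups lower against them by the choice itself. EM organoids had 721 of them lower and 2 higher than adult liver (median -4.09), and the DM organoid 628 lower and 5 higher (median -3.36). Between the media, 156 were higher and 15 lower in the DM organoid. Duct cells had 630 lower and 17 higher than hepatocytes and Lgr5-sorted cells 655 lower and 18 higher, with medians of -3.28 and -3.41. At day 3 after CCl4 111 were higher and 77 lower than in whole liver (median -0.10), and at day 13 164 higher and 11 lower (median 0.38), but whole liver itself had 214 lower and 4 higher than adult liver (median -0.54). A minimum of 1 log2 unit gave 1417 genes and a minimum of 3 gave 433.

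The tissues that served as outgroups showed their own genes. In muscle, Myl1, a myosin light chain, was higher (adult liver at least 912-fold lower), and for skeletal muscle genes, 15 of 15 were lower (median -5.53, or -5.45 with bounds, adjusted p = 4.32e-07, adjusted p = 0.213 with an estimated correlation) in adult liver.
Against white adipose tissue, 12 of 13 were lower (median -3.42, or -3.18 with bounds, adjusted p = 4.54e-08) for adipocyte genes, and the collagen genes Col1a1 (-8.95 ± 0.32) and Col3a1 (-7.76 ± 0.39) were lower in liver.
Against brown adipose tissue, 8 of 10 were lower (median -4.69, or -4.15 with bounds, adjusted p = 9.33e-05) for brown fat genes.
Against pancreas, 17 of 17 were lower (median -7.87, adjusted p = 3.24e-14, adjusted p = 0.0955 with an estimated correlation) for exocrine genes, such as Cpb1 (-12.22 ± 1.36) and Reg1 (-13.04 ± 1.44), and 8 of 10 were lower (median -3.87, or -3.30 with bounds, adjusted p = 2.25e-06, adjusted p = 0.0955 with an estimated correlation) for islet genes. Hepatocyte secreted proteins were higher in liver than in pancreas, 21 of 22 were higher and 1 lower (median 4.96, or 4.49 with bounds, adjusted p = 3.24e-14, adjusted p = 0.088 with an estimated correlation). Adult liver differed from muscle in 7508 genes (3335 higher, 4173 lower), from brown adipose tissue in 6122 (2793 and 3329), from pancreas in 6100 (2656 and 3444) and from white adipose tissue in 5861 (2814 and 3047). The median of all genes moved to -0.22 against brown adipose tissue and 0.17 against pancreas with Agilent's log ratio, and with Cy3 alone to 0.25 against muscle, 0.18 against white adipose tissue and -0.57 against pancreas.

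Similarity across genes was measured as the mean Pearson r of array pairs, after each gene was centred on the mean of the 13 groups. Genes are not independent replicates, so no p is given. It was 0.64 between DM and EM organoids, -0.37 between EM organoids and adult liver, -0.27 between the DM organoid and adult liver and 0.11 between EM organoids and duct cells. Lgr5-sorted cells stood at 0.48 to duct cells and at -0.31 to hepatocytes, with their own pair of arrays at 0.69. Without centring, EM organoids and adult liver stood at 0.35, the DM organoid and adult liver at 0.43 and Lgr5-sorted cells and hepatocytes at 0.27, so these signs depend on the centring.

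**Figure D3:**
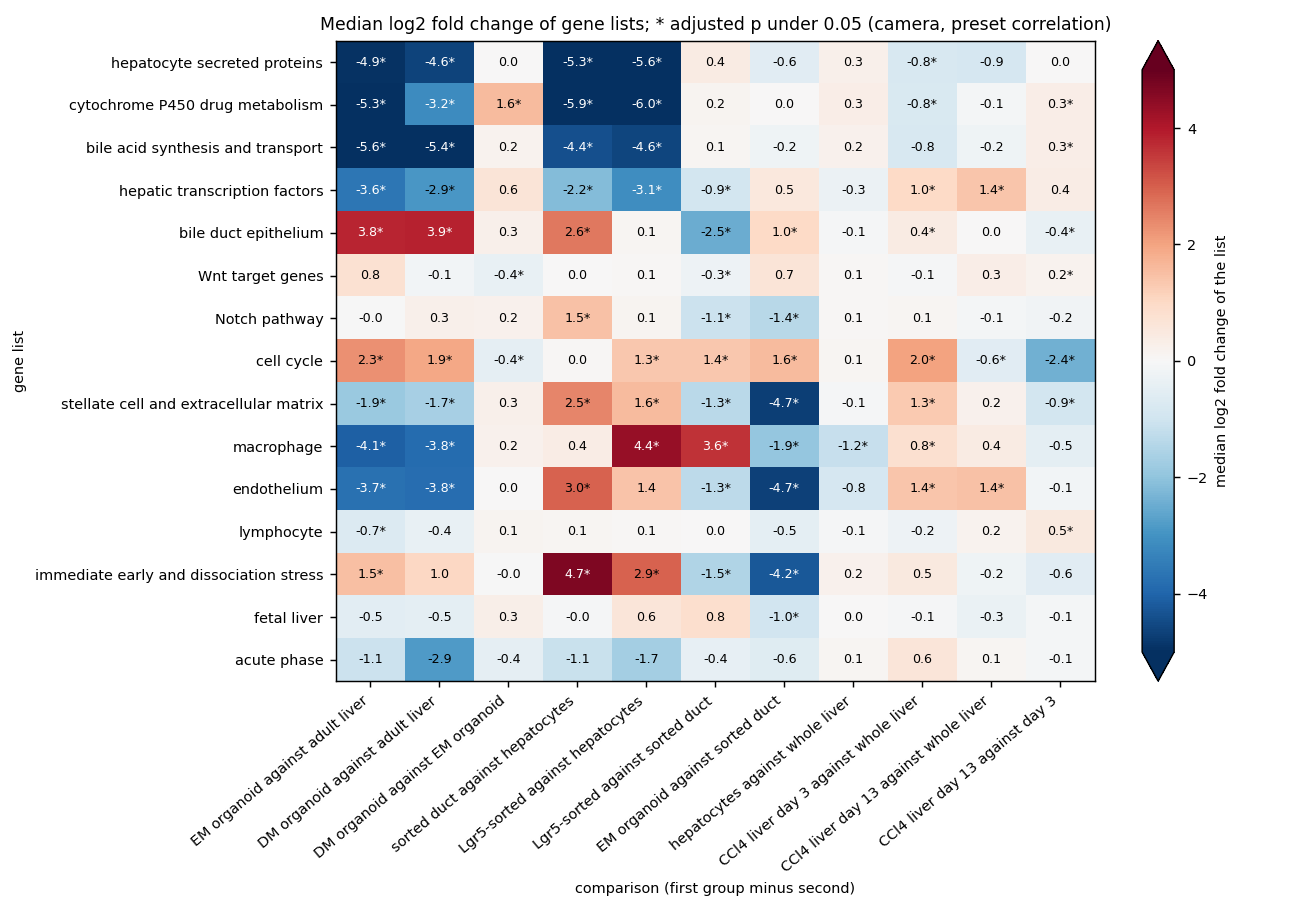
Median log2 change of the members of 15 gene lists (vertical axis) in 11 comparisons (horizontal axis), with an asterisk where camera gave an adjusted p under 0.05. Bile duct epithelium had medians of 3.82 in EM organoids against adult liver and -2.48 in Lgr5-sorted against duct cells.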

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

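The comparison of the times after CCl4 was planned, the tests of cell cycle genes against sex and of macrophage genes outside the list were set before their results were seen, and all other tests in this part were chosen after. The test of the difference between day 13 and day 3 after CCl4 itself called 1185 genes, with a median of -2.39 for the cell cycle list, Xist at 5.98 and Eif2s3y at -4.04, so the groups differ. Spike-in control spots, which no comparison uses, held signal on every array, from 0.0239 times the 99th percentile of the probes on pancreas replicate 2 to 4.62 times on brown adipose replicate 1, with adult liver replicates at 1.30 and 0.171. The reference channel, used only within ratios, also held a signal, with liver-enriched genes higher by a median of 1.69 on adult liver than on muscle arrays.

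X-linked, Y-linked and sex-dependent genes differed between the times after CCl4. Time after CCl4 alone would leave Y-linked genes in place, and the median change of Ddx3y, Eif2s3y and Kdm5d, -3.93, argues against it as their cause (Uty was above background at neither time). Xist (detected at day 13 only) and Ddx3y (day 3 only) go with animals of different sex. Of 156 other genes that set the whole liver array without Ddx3y apart, 62.2% differed the same way between the times (Fisher exact p = 0.0055). That missed the 75% set, so for these sex cannot be told from other differences. For the cell cycle genes, animals of different sex cannot be told apart from time after CCl4: 0 of 29 called members differed in the same direction by 1 log2 unit or more between an Xist-positive whole liver and Y-positive hepatocytes of 1 slide, but these undamaged samples lay a median of -1.98 from day 3, so a sex difference in division after damage would not show.

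Lgr5-sorted arrays had macrophage genes high and bile duct genes mostly not well above background. Low signal is argued against for the 10 duct members that would stay above the detection floor when scaled from the duct arrays, as 2 were detected on both arrays, against 83.8% of 2203 genes scaled alike (Fisher exact p = 1.48e-05), while for the 12 that would fall below it low signal cannot be told apart from absence. Macrophages among the sorted cells, which a sort for Lgr5 should remove, may account for the first: 25 macrophage genes outside the list were higher than in duct cells by a median of 2.30, 21 of them called. Detection on both arrays reached 16 of 20 members, as in whole liver and duct cells, 11 of 15 for endothelium, 13 of 22 for hepatocyte secreted proteins, 8 of 22 for stellate and matrix genes, 1 of 13 for lymphocytes and 0 of 8 for erythroid genes. Lgr5-expressing cells with this profile cannot be told apart from cells without Lgr5: it was detected on 0 of these arrays, but at its share of signal in EM organoids it would reach 30.3 and 27.4, against floors of 24.0 and 56.0.

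Ratios of abundant liver genes were smaller than their Cy3 differences. A reference RNA rich in these transcripts would give the same Cy5 signal on every array, and a lower quartile of 0.41 (upper 3.96) for liver-enriched genes, adult liver minus muscle arrays, argues against it. Carry-over of sample signal into the reference channel may be the cause, given the median of 1.69 for these 758 genes beside -0.0026 for all genes, and 3.55 the other way for 15 muscle genes. No biological explanation was tested.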

How the results depend on the processing

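Groups of 1 to 3 arrays limit every value, and signal over background limits folds of undetected genes to bounds and weighs most on Lgr5-sorted cells among the liver samples. The alternatives with scan day as a block, with only genes above background in the higher group, and with cameraPR were chosen after seeing the data, the others before. Quantiles between arrays leave ratios unchanged and no fold minimum can only add calls, so these test nothing for single genes, and the series matrix repeats Agilent's log ratio. Over the other alternatives, 5044 values of single genes kept direction and side of the threshold, 391 lost and 19 gained it and 12 reversed. For lists these were 2163, 100, 92 and 2, and 288 counts stayed within 1.5 times while 34 did not. Where no cause is named the cause was not tested.

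Agilent's log ratio called 1160 genes for DM against EM organoids, 7677 for duct cells and 6990 for Lgr5-sorted cells against hepatocytes, 4997 for Lgr5-sorted against duct cells, 409 for hepatocytes and 414 for day 13 against whole liver, and 261 for whole against adult liver. For day 13 against whole liver it turned Cyp3a13 to -0.38 and Rhbg to -0.049. Its similarities were -0.30 (DM and adult liver), 0.26 (Lgr5-sorted and duct) and -0.16 (Lgr5-sorted and hepatocytes), and those of Cy3 alone -0.33, 0.31 and -0.055. In the order of those counts Cy3 alone gave 1325, 7395, 7717 and 6625, then 196 for day 13 against whole liver, 786 for whole against adult liver and 12467 for EM organoids against Lgr5-sorted cells, and turned Lrat to -0.48 for day 13 and 0.34 for whole against adult liver. Without a fold minimum, which by construction calls more, there were 3670 for Lgr5-sorted against duct cells, 3362 for day 3 and 1756 for day 13 against whole liver, 1820 between these times, 7974 for EM organoids against Lgr5-sorted cells, 2576 for whole against adult liver, and 11936, 9350 and 10000 for adult liver against muscle, white and brown adipose tissue.

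With the 2 groups alone, limma called 1462 between days 3 and 13 and 2837 for Lgr5-sorted cells against hepatocytes. Whole against adult liver gave 9 (5430 at an unadjusted p under 0.05). Lgr5-sorted against duct cells (3862) and hepatocytes against whole liver (1582) gave 0. With adult liver in place of whole liver day 13 gave 299 genes, and 281 with all 4 undamaged livers. Adult liver turned Sult2a2 (0.95) and Lgr5 (-1.39) at day 3, and at day 13 the cell cycle median (0.0004), Akr1b3 (0.23), Lgr5 (-0.036), Sp5 (-1.09), Lrat (-0.29), Cyp3a13 (-0.0010) and Rhbg (-0.0002). Scan day as a block (correlation 0.202, slide 0.113) gave 242 for hepatocytes against whole liver. Liver-enriched genes were 431 under the strict filter (13811 genes tested), 1417 at 1 log2 unit and 433 at 3.

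Not centred, similarities were 0.75 (DM and EM), 0.43 (DM and adult liver), 0.35 (EM and adult liver), 0.27 (EM and duct), 0.27 (Lgr5-sorted and hepatocytes) and 0.43 (Lgr5-sorted and duct), with Spearman 0.58, -0.18 and -0.25 in that order and -0.065 (Lgr5-sorted and hepatocytes), and under the strict filter 0.46 (Lgr5-sorted and duct). Between replicate differences of groups r ran from -0.11 to 0.44, and a replicate block left every count within 1.5 times, from 191 for hepatocytes against whole liver to 7439 for adult liver against muscle.

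Leaving out each array in turn, with a lone array assumed to vary like other groups, gave 6317 to 6791 for EM organoids and 5427 to 5637 for DM against adult liver, 1700 to 2730 for DM against EM, 4343 to 4927 for duct cells and 3915 to 4709 for Lgr5-sorted cells against hepatocytes, 2135 to 2750 for Lgr5-sorted against duct cells, 55 to 461 for hepatocytes, 1132 to 1883 for day 3 and 401 to 974 for day 13 against whole liver, 777 to 892 between the times, 4885 to 5525 and 4996 to 5833 for EM organoids against Lgr5-sorted and duct cells, 830 to 1520 for whole against adult liver, 721 to 795 for liver-enriched genes, and for adult liver against muscle, white and brown adipose tissue and pancreas 7287 to 7546, 5541 to 6016, 5808 to 6104 and 5558 to 6211. The stress list of Lgr5-sorted against duct cells had a median of -3.55 without Lgr5-sorted replicate 1 and reversed to 0.37 without replicate 2.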

Other observations

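The gene lists below were fixed before the data were examined, and which comparisons to print for them was chosen after their tests were seen. The values are given without an explanation.
In EM organoids against adult liver, 16 of 16 lower (median -5.64, or -4.87 with bounds, adjusted p = 1.29e-14) for amino acid and urea metabolism, 1 of 10 higher and 9 lower (median -5.36, or -4.81 with bounds, adjusted p = 4.21e-07) for periportal hepatocyte genes and 10 of 13 higher (median 1.61, adjusted p = 4.90e-06) for glycolysis. Oxidative stress genes gave 2 of 12 higher and 6 lower (adjusted p = 0.454), and erythroid genes 3 of 8 lower (adjusted p = 0.0875), a list that passed with Cy3 alone (adjusted p = 0.0133).
Against sorted duct cells, EM organoids had 6 of 12 higher and 1 lower (median 1.02, or 1.49 with bounds, adjusted p = 0.0187, adjusted p = 0.291 with an estimated correlation) for intestinal stem cell genes, a call lost with Agilent's log ratio (adjusted p = 0.284) and Cy3 alone (0.0654), and 10 of 17 higher (median 1.13, adjusted p = 0.0046, adjusted p = 0.3 with an estimated correlation) for cholesterol synthesis.

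Duct cells against hepatocytes gave 11 of 14 higher (median 2.41, adjusted p = 7.38e-07, adjusted p = 0.0569 with an estimated correlation) for the response to TGF-beta.
Lgr5-sorted cells against hepatocytes gave 13 of 17 lower (median -1.91, or -1.90 with bounds, adjusted p = 1.13e-10) for cholesterol synthesis and 8 of 13 higher (median 1.27, or 1.33 with bounds, adjusted p = 6.24e-06) for glycolysis, the second lost with Cy3 alone (adjusted p = 0.587).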
